A study of Mus musculus with 6 samples.

How the data were processed

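RNA was measured in popliteal lymph nodes of 6 uninfected mice, 3 fed lean chow and 3 fed a high-fat diet, with 1 single-end sequencing library per mouse. Per the labels' protocols the frozen nodes were pulverized in acid phenol. The same protocols mention both a poly-A enrichment and a library kit used on RNA depleted of ribosomal RNA, so it is not settled which of these RNA pools was sequenced. Per the submitters' processing notes, the authors processed the reads with Trimmomatic 0.32 and Cufflinks 2.0.2 on the mouse genome build mm10. The aligner and the gene annotation are not given in the sources used here. The deposited values are FPKM per the file headers, which stands for fragments per kilobase of transcript, scaled to mapped fragments. Each has a lower and an upper confidence bound on the same FPKM scale. Whether the values were also scaled between libraries is not stated. The table has 23359 genes, 1 row each, and every per-mouse column was matched to a mouse by its name (0 columns were left unused).

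FPKM values are not counts, so no count model was used. All tests were made on log2(FPKM + 1), which understates the change of genes with low values. Genes with a mean FPKM of at least 1 over the 6 libraries were tested (6401 genes). High-fat and lean nodes were compared in R 4.3.3 with limma 3.58.1 (linear model by diet only, moderated with a mean-variance trend and robust hyperparameters, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are high-fat minus lean throughout, with their standard errors (SE). FPKM values are given as mean ± SD over the 3 mice of a diet. With 3 mice against 3, an exact permutation test of a single gene cannot give a p below 0.1, so no such test was used for a call.

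Before the data were examined, 37 gene lists were fixed for cell types of the node, germinal centre and antibody responses, diet and metabolism, tissues that may be dissected with a node, and RNA quality. Lists with at least 3 tested members (32 lists) were compared with limma's camera with a preset inter-gene correlation of 0.01, adjusted over these lists. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in one direction, served as alternatives. For each list the members past the gene-level threshold were counted adjusted over all genes tested and, beside this, adjusted over the list alone. The list of immunoglobulin heavy chain constant regions had 0 members in the table and could not be tested. The genes named were also set beforehand. They are the 12 largest rises and 12 largest falls among called genes whose 3 libraries of one diet all lay above the 3 of the other, with predicted gene models skipped (2 among the rises, 0 among the falls), up to 3 members with the smallest p of each list, and 26 symbols of germinal centre, antibody and adipokine biology where the table has them (18 did). Of the genes so chosen, 4 are not reported here, and no other genes took their places. Genes chosen after their values were seen are marked as such.

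Depth was read from the confidence bounds, since FPKM carries no read totals. Among genes with a wide interval, the relative error fell on the steps of 1 to 5 reads, and 71.9% to 73.8% of such values lay within 0.02 of a whole read number. The FPKM that 1 read was worth was then compared between libraries gene by gene, and its inverse is called the relative depth here. If the deposited values were scaled between libraries, it reflects that scaling and need not be the depth. The absolute depth is unknown. An exact 0 in such a table can be a failed estimate, so genes are described as listed at 0. In total 4351 rows share their locus with another row, and reads of overlapping genes or of near-identical copies cannot be told apart here. Gene coordinates are 1-based and come from the GENCODE M21 annotation of the same genome assembly (GRCm38, the mm10 build), or from the deposited table where the symbol is not in that annotation. Of the rows, 93.0% carry a symbol found in GENCODE M21.

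Transcript length and GC content were taken as the median over the GENCODE basic transcripts of a gene and were available for 6042 tested genes (94.4%). This median can differ from the length of the transcript expressed in the nodes, and removal of the trend then misjudges the gene. Removal of a loess trend on log2 length and GC content (span 0.4) from each library's deviation from the gene mean, the same with the mean level as a further term, and a restriction to protein-coding rows (5782 genes) were alternatives added after the data were examined. Removal of the length and GC trend was also combined with the replicate block, with an estimated correlation and with leaving out each library. Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean FPKM of 5, upper-quartile scaling, quantile normalization, scaling to TPM, the mouse number as a replicate block, limma array weights, limma without trend and robust settings, a per-gene permutation test, and leaving out each library in turn.

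The code was tested on simulated data for the diet comparison. On 6401 simulated genes, of which 200 were changed, limma recovered 91% of those changed by 0.5 and 96% of those changed by 1 on the log2 scale, with 8 false calls among 195. With no simulated change it made 0 calls. A simulated length trend alone, of the size seen in the libraries, gave 570 calls among 6042 genes, and 0 after the trend was removed. That trend was the same in all 3 high-fat libraries, and genes varied independently in all these simulations. The real trends differed, with medians of -0.16, -0.06 and -0.18 for the shortest genes in high-fat replicates 1, 2 and 3. The simulations therefore test the code and do not bear on the real calls. Of 32 simulated lists, the 1 list shifted by 0.3 was called, along with 1 other. Summaries and plots were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.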

Results

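Popliteal lymph nodes, which drain the hind foot, were collected from uninfected C57Bl6/J mice after 12 weeks on a chow with 10% of calories from fat (lean) or on a diet with 60% of calories from fat (high-fat), begun at 5 weeks of age. Each diet was represented by 3 mice and 3 RNA-seq libraries. Summed FPKM was 139729 ± 3801 (SD, n = 3) in lean and 111542 ± 7794 (SD, n = 3) in high-fat libraries, while 6206 ± 48.6 and 6577 ± 83.4 genes reached an FPKM of 1. Relative to the first lean library, the inferred depth was 1 to 1.22 in lean and 1.27 to 1.37 in high-fat libraries. For genes with 1 read the squared relative error was 0.86 to 1.02 in lean and 1.07 to 1.15 in high-fat libraries. It thus parted the diets as the inferred depth did, which points to values scaled between libraries. The inferred depth may then be the scaling factor, and whether the high-fat libraries were the deeper ones is not settled. The half-width of the deposited confidence interval had a median of 30.6% of the FPKM value in tested genes in both diets.

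The study concerns foot infection and antibody immunity in obese, diabetic mice, and the comparison asks how nodes differed between diets before any infection. In high-fat nodes, transcripts of the glucocorticoid-induced leucine zipper Tsc22d3, the stress-induced mTOR inhibitor Ddit4, the chemokine receptor Cxcr4 and the B cell receptor inhibitor Cd22 were about 1.9 to 2.2 times as high as in lean nodes on the log2(FPKM + 1) scale. The endothelial tight junction gene Cldn5 and the ion transport regulator Fxyd6 were lower, at 8.60 ± 0.952 against 16.9 ± 1.89 FPKM and 2.98 ± 0.164 against 5.84 ± 0.644 FPKM (SD, n = 3). As groups, mature B cell genes were higher, with a median log2 fold change of 0.24 over 19 members of which 5 passed, and cytoplasmic ribosomal protein genes were lower, with a median of -0.46 over 20 members of which 19 passed. Both had an adjusted p = 0.92 with an estimated correlation, the B cell median was 0.10 without lean replicate 2, and the ribosomal list was at -0.05 and not called after quantile normalization. Scaled to TPM, which raised the values of most genes in high-fat nodes, the ribosomal median was -0.14 with 5 of 20 members lower. Of 6401 genes tested with limma, 847 were higher and 878 lower in high-fat nodes, together 26.9% of those tested. Most changes were small: the median absolute log2 fold change of the called genes was 0.34, and 8 reached 1, among them microRNA rows listed at 0 in the high-fat libraries.

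Tsc22d3 (chromosome X, 140539528 to 140600659, GRCm38) rose from 4.82 ± 1.09 to 11.6 ± 2.07 FPKM, a log2 fold change of 1.12 (SE 0.17, limma adjusted p = 0.0079). Ddit4 (chromosome 10, 59949669 to 59951834) rose from 4.29 ± 0.807 to 9.24 ± 0.756 FPKM, a log2 fold change of 0.96 (SE 0.11, limma adjusted p = 0.0053). Cxcr4, which guides lymphocytes toward Cxcl12 (chromosome 1, 128588199 to 128592293), rose from 8.53 ± 1.70 to 16.8 ± 1.61 FPKM, a log2 fold change of 0.91 (SE 0.13, limma adjusted p = 0.0062). Each of these genes was higher in 3 of 3 high-fat libraries than in any lean library, which the rule for naming them required. Myh9, a nonmuscle myosin heavy chain, and Iqgap1, a cytoskeletal scaffold protein, rose by 1.09 and 0.90 on the log2 scale. The complement component C3 rose by 0.92 and the lymphoid transcription factor Ikzf3 by 0.89. Cd22 (chromosome 7, 30865402 to 30880342) rose from 2.41 ± 0.638 to 5.29 ± 1.08 FPKM, by 0.89. Hnrnpa1, Hnrnpu and Son, which encode RNA-binding proteins, rose by 0.90, 0.89 and 0.89, although the Hnrnpa1 row shares its locus with other rows. The largest rise was listed for Mir719, from 1.39 ± 0.452 to 8.90 ± 1.84 FPKM, in a microRNA row of 110 nt that also shares its locus.

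Cldn5 (chromosome 16, 18776847 to 18778262) fell by 0.90 on the log2 scale (SE 0.10, limma adjusted p = 0.0045) and Fxyd6 (chromosome 9, 45370185 to 45396159) fell by 0.78 (SE 0.08, limma adjusted p = 0.0034). Both were lower in 3 of 3 high-fat libraries than in any lean library, again as the rule required. Gpx3, the extracellular glutathione peroxidase, went from 13.0 ± 0.702 to 7.31 ± 1.46 FPKM, a log2 fold change of -0.77. Sepp1, the plasma selenium carrier, went from 353 ± 68.8 to 209 ± 35.8 FPKM, a log2 fold change of -0.75. The iron exporter Slc40a1 fell by 0.80, the mast cell tryptase Tpsb2 by 0.87, the cytochromes P450 Cyp2e1 and Cyp2f2 by 1.09 and 0.81, the lectin Cd209d by 0.73 and the adhesion molecule Ninj1 by 0.73. The microRNA rows Mir1247 and Mir717 were listed at 0 in all 3 high-fat libraries and at 6.40, 6.84 and 6.24 and at 2.58, 2.71 and 2.25 FPKM in the lean libraries. Their annotated transcripts are 82 and 109 nt long and share loci with other rows, so these values are uncertain.

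**Figure D1:**
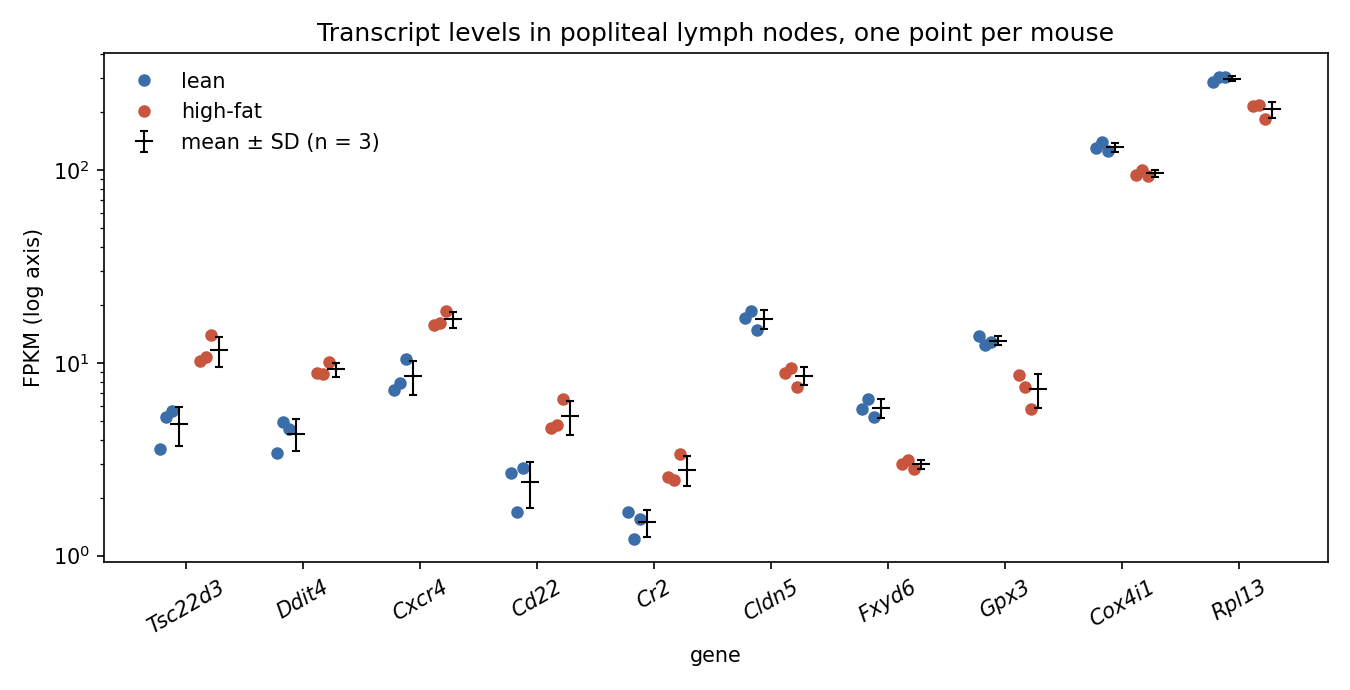
FPKM (log axis) of 10 named genes in the 3 lean (blue) and 3 high-fat (red) nodes, one point per mouse, with the mean and SD beside each group. The groups do not overlap for any of these genes: Tsc22d3, Ddit4, Cxcr4, Cd22 and Cr2 were higher and Cldn5, Fxyd6, Gpx3, Cox4i1 and Rpl13 lower in high-fat nodes. The rule for naming required this of all but Cr2, Cox4i1 and Rpl13, and it held for 46.4% of all tested genes.

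Among mature B cell genes, 5 of 19 tested members rose and 0 fell, with the same counts adjusted over the list alone, and camera called the list higher (adjusted p = 0.0038, but adjusted p = 0.92 with an estimated correlation). Of all tested genes 26.9% were called in either direction. Counts of called members near that share, such as this one, set no list apart by themselves. Cr2, the complement receptor of follicular and marginal zone B cells (chromosome 1, 195136811 to 195176716), rose from 1.49 ± 0.246 to 2.79 ± 0.488 FPKM (log2 fold change 0.60). Cxcr5, the receptor that brings B cells into follicles (chromosome 9, 44511787 to 44561877), rose from 6.19 ± 1.11 to 9.71 ± 1.03 FPKM (0.58), and the signalling scaffold Bank1 rose by 0.64. The call was also lost by fry (adjusted p = 0.38) and without lean replicate 2 (camera adjusted p = 0.072), when the median went from 0.24 to 0.10. The median deviation of the list from the gene means was 0.06, -0.39 and -0.05 in the lean and -0.01, 0.19 and 0.20 in the high-fat libraries. The range over all 28 alternatives was 6.0e-06 to 0.92, with 0.00039 and a median of 0.27 when the length and GC trend was removed.

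Germinal centre B cell genes were not called as a list (camera adjusted p = 0.50). Their median was 0.13, with 0.04 without high-fat replicate 3, 0.24 without lean replicate 1 and -0.05 with the length, GC and level trend removed. Of 5 tested members, 2 rose and 1 fell, also when adjusted over the list alone. Bcl6, the transcription factor of germinal centre B cells (chromosome 16, 23965052 to 23988852), rose by 0.28 (limma adjusted p = 0.018) and the semaphorin receptor Plxnb2 by 0.30. Both calls ended when the length and GC trend was removed, with log2 fold changes of 0.14 for Bcl6 and 0.12 for Plxnb2, and 0 members of the list were then called. S1pr2 (0.13) did not pass. Plasma cell genes gave 2 rises among 11 tested members, Slamf7 by 0.36 and Irf4 by 0.25, also over the list alone, while Sdf2l1 (-0.20) did not pass (camera adjusted p = 0.70; median -0.04, mean 0.00, direction of the test upward). The plasma cell median was 0.06 without lean replicate 1 and -0.19 without lean replicate 3. The joining chain Igj was 124 ± 46.3 FPKM in lean and 131 ± 11.4 FPKM in high-fat nodes, a log2 fold change of 0.16 that did not pass. Prdm1 was near the floor of the table, at 0.161 ± 0.0191 and 0.225 ± 0.0478 FPKM. Immunoglobulin heavy chain constant genes were not analysed here.

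T follicular helper genes gave 1 rise and 1 fall among 7 tested members, with the same counts over the list alone (camera adjusted p = 0.68, median 0.04, and 0.01 without lean replicate 2). The costimulator Icos rose by 0.34, the adaptor Sh2d1a fell by 0.41, and Slamf6 was at 0.13 without passing. Il21 (0.0272 ± 0.00523 and 0.0762 ± 0.0545 FPKM) and Cd40lg (0.503 ± 0.0378 and 0.619 ± 0.160 FPKM) lay below the level tested. Follicular dendritic cell genes had 1 rise in 6, also over the list alone (camera adjusted p = 0.38). Their median was 0.06, with -0.01 without high-fat replicate 2 and 0.13 without high-fat replicate 1, and the list was called higher with a mean FPKM of at least 5 (adjusted p = 0.042, range over alternatives 0.042 to 0.92). Clu rose by 0.48, whereas Mfge8 (0.22) and Fcgr2b (0.08) did not pass. The B cell chemoattractant Cxcl13 was 57.7 ± 6.03 FPKM in lean and 57.6 ± 15.5 FPKM in high-fat nodes. The B cell survival factor Tnfsf13b had a log2 fold change of -0.15 that did not pass. T cell genes went both ways, with 2 rises and 2 falls in 19, also over the list alone (camera adjusted p = 0.36, median 0.07, but -0.00 without lean replicate 1). Cd3e rose by 0.43 and Il7r by 0.21, and Cd3d fell by 0.51. Of the regulatory T cell list only Tnfrsf18 (-0.23) and Tnfrsf4 (-0.18) were tested. Neither passed over all genes, while 1 of these 2 was lower adjusted over the list alone.

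Cytotoxic lymphocyte genes fell in 3 of 5 tested members, also over the list alone, namely Ccl5 by 0.36, Klrd1 by 0.36 and Nkg7 by 0.30 (0.00 when scaled to TPM). Of these calls, 0 of the 3 held with the length and GC trend removed. Camera did not call this list (adjusted p = 0.15, median -0.34), but fry did (adjusted p = 0.036), and the range over its 28 alternatives was 0.035 to 0.92. Macrophage genes fell in 3 of 11, and in 4 of 11 adjusted over the list alone (camera adjusted p = 0.16, median -0.22). The complement genes C1qc and C1qa were down by 0.48 and 0.44 and the lysozyme Lyz2 by 0.31. Scaled to TPM, which raised the median log2 fold change of all genes by 0.30, the macrophage median was 0.07. Camera then called the list lower (adjusted p = 0.043). Lyz2 was at 0.12 after quantile normalization and 0.01 when scaled to TPM. Without lean replicate 3 the macrophage list was called lower (camera adjusted p = 0.041, range over alternatives 0.0089 to 0.92). In the lipid-associated macrophage list Apoe rose by 0.38, 1 of 6 members in either adjustment, and Cd9 (-0.23) and Lgals3 (-0.20) did not pass (camera adjusted p = 0.94; median -0.08, mean 0.00, direction downward). Dendritic cell genes gave 3 falls and 1 rise in 7, also over the list alone (camera adjusted p = 0.48, median -0.28, which was -0.13 without lean replicate 2, -0.18 without high-fat replicate 1 and -0.43 without high-fat replicate 2). The list was called lower when scaled to TPM (adjusted p = 0.044, range over alternatives 0.044 to 0.96). Siglech fell by 0.44 and Clec10a by 0.43, and Fscn1 rose by 0.35. Among 7 mast cell and eosinophil genes Tpsb2 alone fell, in either adjustment, with Cma1 at -0.69 and Cpa3 at -0.65 not passing (camera adjusted p = 0.16, median -0.61, and -0.31 without lean replicate 1). The mast cell list was called lower when scaled to TPM (adjusted p = 0.00038, range over alternatives 0.00038 to 0.96) and with no filter (0.0059). Neutrophil genes gave 1 rise in 6, Cxcr2 by 0.32, in either adjustment, with Retnlg (-0.30) and Ngp (0.93) not passing (camera adjusted p = 0.47, median 0.21, but -0.05 without high-fat replicate 2 and 0.72 without high-fat replicate 1). With the length and GC trend removed and without high-fat replicate 1 this list was called higher (adjusted p = 0.018, range over alternatives 0.018 to 0.96).

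Genes of antigen presentation by MHC class II gave 1 rise and 1 fall in 11, and 1 rise and 0 falls over the list alone (camera adjusted p = 0.94; median -0.04, mean 0.02, direction downward), and the list was called upward after quantile normalization (adjusted p = 0.0079, range over alternatives 0.0079 to 0.99). Their master regulator Ciita rose from 0.739 ± 0.175 to 2.09 ± 0.588 FPKM, by 0.82, the protease Ctss fell by 0.25 (0.08 when scaled to TPM), and the class II chain H2-Aa (-0.18) did not pass. Interferon response genes gave 1 fall in 11, Bst2 by 0.53, in either adjustment, with Gbp4 (0.37) not passing (camera adjusted p = 0.94, median -0.34). Without lean replicate 1 the interferon median was 0.17, and the list was called lower when scaled to TPM (adjusted p = 0.040, range over alternatives 0.040 to 1.00). Among 8 inflammatory cytokines and chemokines Lta rose by 0.23 and Il18 fell by 0.36, and over the list alone 2 rose and 1 fell, with Csf1 at 0.22 (camera adjusted p = 0.91; median -0.02, mean -0.01, direction upward), and the median was 0.14 without high-fat replicate 1. Il6 (0.0581 ± 0.0220 and 0.0663 ± 0.0181 FPKM) and Tnf (0.511 ± 0.101 and 0.443 ± 0.0469 FPKM) lay below the level tested.

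Of 8 fibroblastic reticular genes 0 passed in either adjustment, with Cxcl12 at -0.35, Des at -0.19 and Bst1 at 0.14 (camera adjusted p = 0.91, median -0.08). That median was -0.14 without high-fat replicate 2 and -0.03 without high-fat replicate 3. Of 5 high endothelial venule genes 0 passed in either adjustment, with Glycam1 at 0.81, Gcnt1 at 0.19 and Fut7 at 0.12 (camera adjusted p = 0.36, median 0.12). The venule median was 0.05 without high-fat replicate 2 and 0.15 without lean replicate 3. The lymphatic markers moved apart, Lyve1 rising by 0.45 and Mmrn1 falling by 0.36, with Marco at -0.09, and the 3 members gave 1 rise and 1 fall in either adjustment (camera adjusted p = 0.94; median -0.09, mean 0.00, direction downward). The lymphatic median was -0.31 without high-fat replicate 2 and 0.03 without high-fat replicate 1. Smooth muscle and vessel wall genes rose in 2 of 4, and in 3 of 4 over the list alone, with Acta2 up by 0.70 and Pecam1 by 0.32, and Cdh5 at 0.27 not passing over all genes (camera adjusted p = 0.16, median 0.30). That list was called higher with no filter (adjusted p = 0.016, range over alternatives 0.016 to 0.92) and with a mean FPKM of at least 5 (0.042). Extracellular matrix genes rose in 3 of 7, Col3a1 by 0.64, Postn by 0.37 and Col1a2 by 0.36, and over the list alone 3 rose and 1 fell (camera adjusted p = 0.15, median 0.15). The matrix median was 0.09 without lean replicate 3 and 0.22 without lean replicate 1. Without lean replicate 1 the matrix list was called higher (adjusted p = 0.046, range over alternatives 0.0035 to 0.92).

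Cytoplasmic ribosomal protein genes fell in 19 of 20 members, also over the list alone, and camera called the list lower (adjusted p = 9.1e-08, median -0.46, and -0.05 after quantile normalization). This call was lost with an estimated correlation (adjusted p = 0.92 with an estimated correlation). Scaled to TPM the ribosomal median was -0.14 with 5 of 20 members lower, and camera still called the list lower (adjusted p = 2.8e-16). Rpl13 (chromosome 8, 123102350 to 123105244) went from 297 ± 9.37 to 206 ± 19.3 FPKM, a log2 fold change of -0.53, and Rpl27 fell by 0.47. These genes have many processed copies in the genome, and reads shared with them cannot be told apart here. Genes of oxidative phosphorylation fell in 10 of 17, and in 11 of 17 over the list alone (camera adjusted p = 0.0061, but adjusted p = 0.92 with an estimated correlation). Their median was -0.30. Scaled to TPM, which raised the median log2 fold change of all genes by 0.30, it was 0.02, and camera still called the list lower (adjusted p = 0.040). Among them were the respiratory chain subunits Cox4i1, from 131 ± 7.20 to 96.1 ± 3.81 FPKM, Cox6c, by 0.47, and Uqcrfs1, by 0.36. Cell cycle genes rose in 3 of 8, and in 5 of 8 over the list alone (camera adjusted p = 0.038, but adjusted p = 0.92 with an estimated correlation; median 0.22). The ribonucleotide reductase subunit Rrm2 rose by 0.38 and the replication licensing factors Mcm3 by 0.26 and Mcm2 by 0.23. The proliferation marker Mki67 was at 0.0516 ± 0.0222 FPKM in lean and 0.436 ± 0.229 FPKM in high-fat nodes, below the level tested. For each of these 3 lists 0.92 was the highest adjusted p over its alternatives, against lowest values of 2.8e-16 (ribosomal), 2.5e-06 (oxidative phosphorylation) and 4.2e-06 (cell cycle). The ribosomal and oxidative phosphorylation calls were also lost after quantile normalization (adjusted p = 0.34 and 0.14) and by fry (0.055 and 0.083). The oxidative phosphorylation call was lost with the length, GC and level trend removed (0.091) and with a mean FPKM of at least 5 (0.089). The cell cycle call was lost by fry (0.20), when scaled to TPM (0.087), with array weights (0.054), without lean replicate 2 (0.095), high-fat replicate 2 (0.069) or high-fat replicate 3 (0.063).

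Of 14 adipocyte genes 0 passed in either adjustment (camera adjusted p = 0.91; median 0.13, mean -0.10, direction upward), and the median was -0.12 without lean replicate 3 and -0.14 without high-fat replicate 3. Adiponectin, Adipoq, was 8.95 ± 5.85 FPKM in lean and 6.86 ± 4.18 FPKM in high-fat nodes. Leptin, Lep, was 1.28 ± 1.34 and 1.94 ± 1.43 FPKM, and the leptin receptor Lepr had a log2 fold change of -0.21. The adipocyte genes with the smallest p were Cfd (-2.06, in a row whose locus is shared with many others), Pnpla2 (0.15) and Cebpa (-0.08). Fatty acid oxidation genes rose in 2 of 12, and in 1 of 12 over the list alone, Hadha by 0.35 and Cpt1a by 0.26 (camera adjusted p = 0.68; median -0.00, mean 0.02, direction upward). Lipid synthesis genes rose in 2 of 6, and in 3 of 6 over the list alone, Hmgcs1 by 0.39 and Acly by 0.26, with Srebf1 at 0.17 not passing over all genes (camera adjusted p = 0.16, median 0.21). The lipid synthesis median was 0.12 without high-fat replicate 3, and the list was called higher with no filter (adjusted p = 0.020, range over alternatives 0.020 to 0.92). Glucose and insulin signalling genes rose in 3 of 10, also over the list alone, Hk1 by 0.44, Foxo1 by 0.42 and Pfkp by 0.21 (camera adjusted p = 0.23, median 0.05). Genes of the unfolded protein response rose in 3 of 12, also over the list alone, Pdia4 by 0.59, Atf4 by 0.28 and Sel1l by 0.26 (camera adjusted p = 0.46, median 0.03, but -0.01 without lean replicate 2 or without high-fat replicate 2).

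Red blood cell genes had a median log2 fold change of -1.72 with 0 of 5 members passing in either adjustment (camera adjusted p = 0.15), and the list was called lower without high-fat replicate 1 (adjusted p = 0.0074, range over alternatives 7.0e-06 to 0.92). Without high-fat replicate 3 the median was -0.93. Hba-a2 was 243, 452 and 335 FPKM in the lean and 254, 119 and 34.0 FPKM in the high-fat libraries, with a log2 fold change of -1.70. Hbb-b2 (-1.72) and Alas2 (-1.13) did not pass either. In the skeletal muscle list Acta1 rose by 0.76, while Myl1 (-0.41) and Tnni2 (-0.64) did not pass over all genes. Over the list alone 1 of 4 rose and 1 fell (camera adjusted p = 0.94, median -0.26, and -0.14 without lean replicate 2). Acta1 and Acta2 encode near-identical actins. Another actin gene, Actc1, chosen after its values were seen, rose as well, from 20.1 ± 0.909 to 37.4 ± 1.49 FPKM (log2 fold change 0.87). Whether reads were shared between the actin rows was not tested, so these rises are uncertain. The keratinocyte list had 1 tested member, Sfn, which rose by 0.34 in either adjustment. The peripheral nerve list had 2, of which Pmp22 fell by 0.40 in either adjustment and Mbp (0.11) did not pass. Brown adipocyte genes had 0 tested members. Of 10 immediate early and heat shock genes 0 passed in either adjustment, with Hspb1 at -0.29, Ier2 at -0.48 and Nr4a1 at 0.28 (camera adjusted p = 0.68, median -0.29). Without lean replicate 3 the median of this list was 0.15, and the list was called lower when scaled to TPM (adjusted p = 0.041, range over alternatives 0.041 to 0.98). Of 14 replication-dependent histone genes 0 passed in either adjustment, with Hist2h3b at -0.20, Hist1h3a at -0.16 and Hist1h3d at -0.14 (camera adjusted p = 0.38, median -0.10, and -0.01 without lean replicate 2). The histone list was called lower with no filter (adjusted p = 0.036, range over alternatives 0.027 to 0.99).

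**Figure D2:**
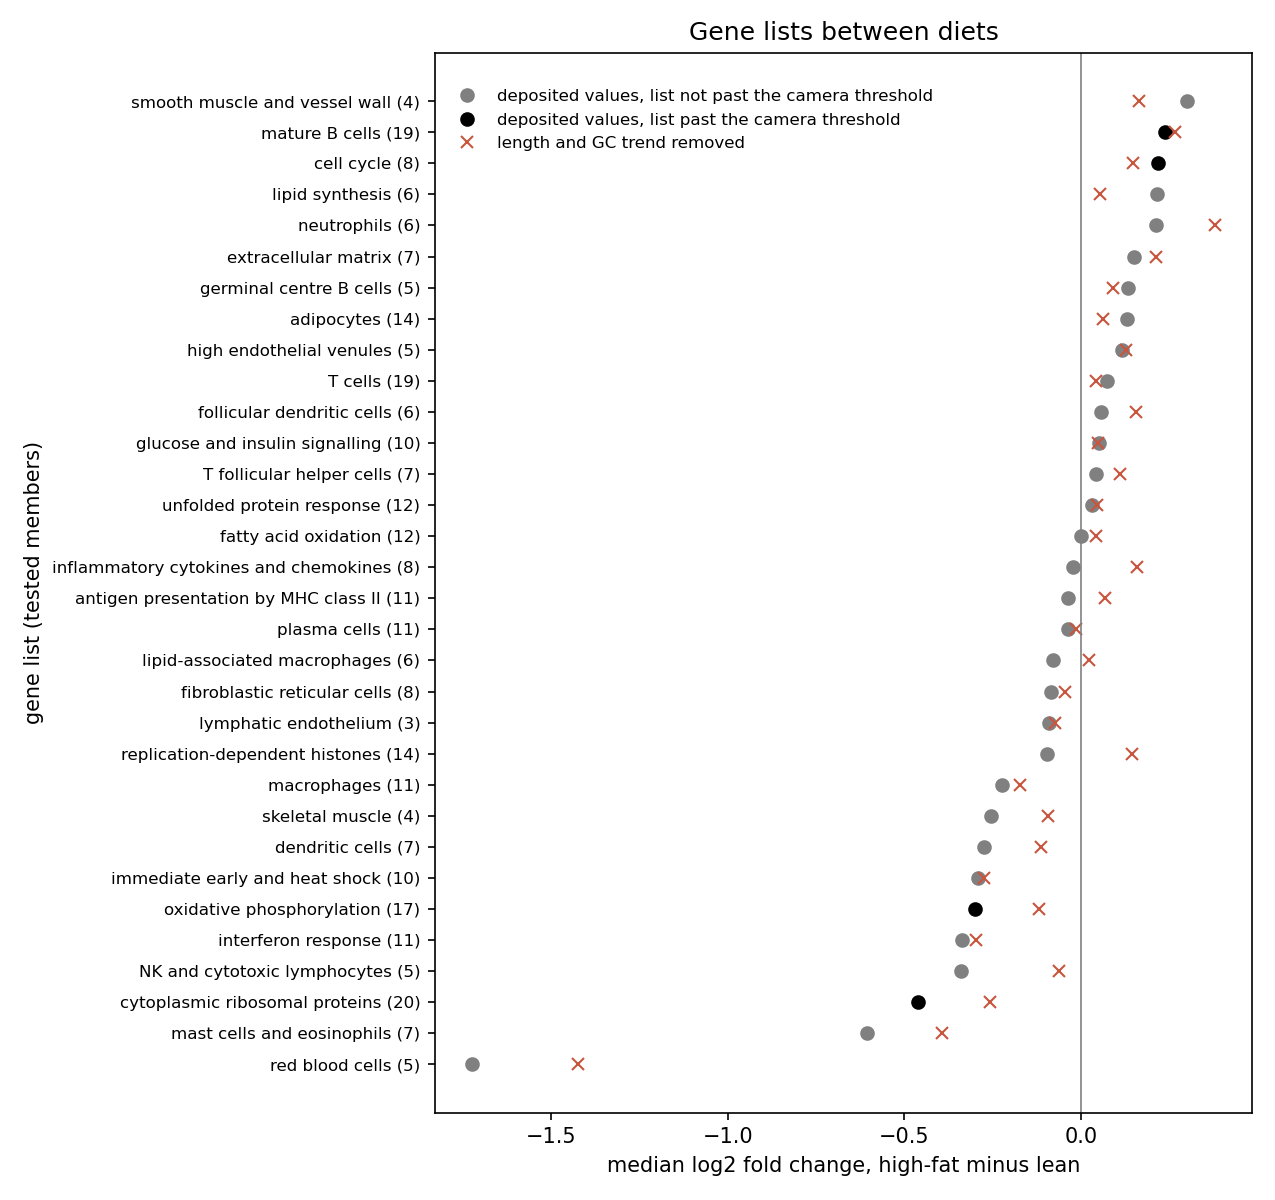
Median log2 fold change (high-fat minus lean, log2(FPKM + 1) scale) of the tested members of 32 gene lists, with the number of tested members in brackets. Dots are the deposited values, black where camera with a preset correlation called the list, and crosses the values with the length and GC trend removed; the ribosomal list moved from -0.46 to -0.26 and the mature B cell list from 0.24 to 0.27.

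The change of a gene was related to the length of its transcript. Across 6042 genes, which are not independent replicates, the log2 fold change correlated with transcript length (Spearman 0.58) and hardly with GC content (-0.04). Genes in the shortest eighth, up to 877 nt, had a median log2 fold change of -0.26, and those in the longest eighth, from 3956 nt, a median of 0.17. Removal of the length and GC trend left medians of 0.003 and 0.06 in these eighths and a Spearman correlation with length of 0.06. With the length and GC trend removed, 463 genes were higher and 329 lower of the 6042, and 645 of 1626 calls kept their direction and their side of the threshold. Among these were Tsc22d3 (1.20), Ddit4 (1.00), Cxcr4 (0.97), Cd22 (0.73), Cr2 (0.53), Cldn5 (-0.82), Fxyd6 (-0.75) and Gpx3 (-0.71). Of 80 named genes that were called and had a length, 32 were no longer called. In some of these the log2 fold change stayed about as large, as in Hnrnpu (0.89 to 0.79), Cyp2e1 (-1.09 to -0.999), Clu (0.48 to 0.51), Rrm2 (0.38 to 0.40), Cd3d (-0.51 to -0.43) and Il7r (0.21 to 0.17). In others it shrank, as in Ccl5 (-0.36 to -0.05), Nkg7 (-0.30 to -0.06), Il18 (-0.36 to -0.12), Mcm2 (0.23 to 0.07), Sh2d1a (-0.41 to -0.19), Cox6c (-0.47 to -0.18) and Rpl27 (-0.47 to -0.21). The rest included Irf4, C1qa, Lyz2, Bst2, Mcm3, Hadha, Cpt1a, Acly, Foxo1, Pfkp, Sel1l, Col1a2, Pecam1, Pmp22 and Uqcrfs1. The ribosomal list stayed called at a median of -0.26 (camera adjusted p = 4.0e-07) with 8 of 20 members lower, the oxidative phosphorylation list at -0.12 (adjusted p = 0.022) with 2 of 17 lower. Both had a camera adjusted p = 0.87 with an estimated correlation and the trend removed, where all lists lay between 0.87 and 0.93. The cell cycle list was at 0.15 and not called (adjusted p = 0.053), but with the mean level removed too it was called higher (adjusted p = 0.0495, median 0.15). The 792 gene calls with the trend removed became 20 without lean replicate 2, 34 without high-fat replicate 3, 40 without high-fat replicate 1, 348 without lean replicate 1 and 476 without high-fat replicate 2.

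**Figure D3:**
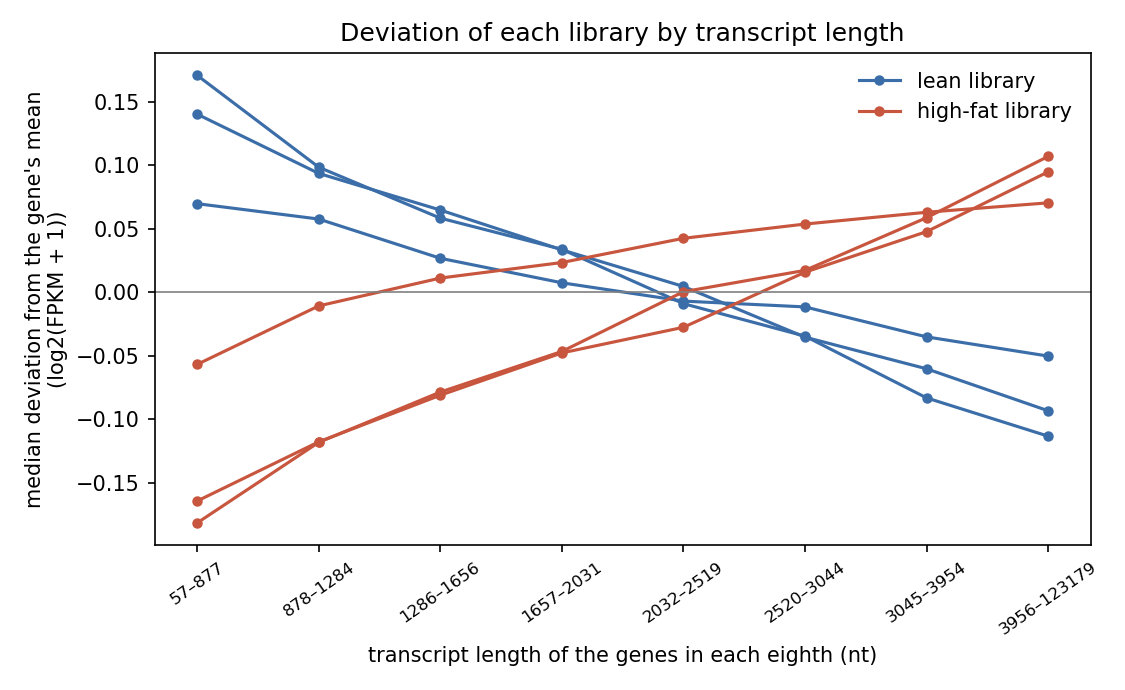
Median deviation of each library from the gene's mean over the 6 libraries, on the log2(FPKM + 1) scale, in eighths of 6042 genes by transcript length (nt). The 3 lean libraries (blue) lie above 0 for the shortest genes and below 0 for the longest, and the 3 high-fat libraries (red) the other way round.

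In all, 1714 of the 1725 called genes had fully separated groups, and 46.4% of all tested genes did, where chance gives 10% for a single gene. A call and a separation rest on the same values, so the first count is no further support. Genes are not independent, and a trend shared by libraries, such as that with length, can separate many at once. The share therefore does not measure an effect of diet. The balance of directions followed the scaling: upper-quartile scaling gave 1145 genes higher and 545 lower, and TPM scaling, which raised the median log2 fold change of all genes by 0.30, gave 2954 higher and 100 lower. The count fell to 830 without lean replicate 2, to 923 without high-fat replicate 1 and to 704 without high-fat replicate 3.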

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

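Removal of the length and GC trend, with or without the mean level or a second change, and the restriction to protein-coding rows were chosen after the data were seen. The number of gene calls, 1725, stayed within 1.5 times under both other pseudocounts, no filter, upper-quartile scaling, quantile normalization, array weights, limma without trend and protein-coding rows only. With no filter 1628 were higher and 548 lower, with 994 of the 1725 calls kept, and quantile normalization kept 1122. The number became 753 with a mean FPKM of at least 5 (125 higher, 628 lower), where fewer genes were tested, and 3054 with TPM scaling. It became 792 with the length and GC trend removed and 601 with the mean level removed too. Without each library in turn the count ranged from 704 to 1647. With the trend removed it ranged from 20 (without lean replicate 2) to 682, with 40 without high-fat replicate 1 and 34 without high-fat replicate 3, and 348 without lean replicate 1 and 476 without high-fat replicate 2. The per-gene permutation test called 0 genes because it cannot go below 0.1, while 2656 genes had an unadjusted limma p under 0.05. Same-numbered mice did not deviate together (correlations -0.29, -0.08 and -0.03 for numbers 1, 2 and 3). With the number as a replicate block 1543 genes were called, and 561 with the trend removed as well; 4 and 3 lists were called. Camera called 4 lists, 12 of 36 with no filter, 10 with TPM scaling, 1 by fry, 0 with an estimated correlation and 0 with an estimated correlation and the trend removed; leaving out single libraries gave 2 to 5 and changed the sign of the median in 12 of the 28 lists not called. Of 2330 values of 127 tested named genes, 254 fell below the threshold, 51 passed it newly and 8 changed sign where one of the values was called. TPM scaling turned Nkg7 to 0.0018, Lyz2 to 0.013 and Ctss to 0.077. It raised the median log2 fold change of all genes by 0.30, so these turns follow from the scaling. Which scaling is closer to the nodes is not known, so the direction of these genes is not settled. Quantile normalization turned Lyz2 to 0.12, Ctss to 0.039 and H2-Aa to 0.30. Removal of length, GC and mean level turned Plxnb2 to -0.045 and Lyz2 to 0.021. The MHC class II list was called upward after quantile normalization (adjusted p = 0.0079) and with the mean level removed (0.0495). The histone list was called upward with the trend removed and without lean replicate 2 (0.042) or high-fat replicate 2 (0.027). Except for the smaller gene and library numbers, the cause was not tested. The unknown absolute depth leaves genes under an FPKM of 1 with little precision.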

Other observations

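The tests chosen only after the result was seen were those of the other splits, of the level within the length trend, of the calls that stayed, and of the length, GC and level trends for the ribosomal and B cell lists, along with every removal of a trend; for the ribosomal list, quantile normalization was added to the test of the level trend after its value was known. The genes of this paragraph were chosen after their values were seen, and each was called in the deposited values and with the length and GC trend removed. Ccr6, a chemokine receptor of naive B cells, went from 3.00 ± 0.314 to 5.48 ± 0.880 FPKM (SD, n = 3; log2 fold change 0.69), the transcription factor Ets1 from 9.82 ± 1.53 to 16.8 ± 1.03 FPKM (0.73), and the D-type cyclin Ccnd2 from 2.03 ± 0.159 to 3.51 ± 0.292 FPKM (0.57). The junction genes Jam3 (8.01 ± 0.906 to 4.86 ± 0.760 FPKM, -0.62) and Cldn11 (1.84 ± 0.293 to 0.872 ± 0.162 FPKM, -0.60) were lower and the pericyte gene Rgs5 (2.31 ± 0.455 to 4.49 ± 0.460 FPKM, 0.73) was higher.

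The median deviation of the neutrophil list from the gene means was 1.48 in high-fat replicate 2 and between -0.54 and 0.05 in the others. That of the red blood cell list was 0.40, 1.56 and 0.68 in the lean and 0.46, -0.49 and -2.40 in the high-fat libraries. The cell proliferation marker Mki67, below the level tested, passed with no filter on low values (log2 fold change 0.44, limma adjusted p = 0.043).

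The gene calls were set against the other ways of dividing the same libraries. The division by diet called 1725 genes, the only 1 of 10 splits with so many, and the highest of the other splits called 2. With 10 splits no share under 0.05 can be reached.

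The first pattern weighed is the rise of log2 fold changes with transcript length: a trend with expression level is argued against, because within sixths of the genes by mean level the median Spearman correlation with length was still 0.52. Genes of low level in no list showed the same rise (Spearman 0.51 over 6094 genes). A length bias of the libraries that spares no kind of gene needs this rise. Such a bias, from RNA integrity, library preparation or a difference in depth, is thus a candidate explanation. Among the 981 calls that ended with the trend removed, the median absolute log2 fold change fell by 48.1% (0.30 to 0.16, median SE 0.08 to 0.07), against 18.4% in those that stayed. The calls were divided by whether they ended, so a larger fall among the ended ones was partly fixed in advance. The fold became smaller in 968 and not in 13. The adjustment became stricter too (largest unadjusted limma p called 0.013, then 0.0065), and 494 of the 981 still had an unadjusted limma p under 0.05. Of the 1626 calls with a transcript length 39.7% stayed. As far as the annotated lengths hold and the removal was complete, this argues against the trend as the whole cause of those. The removal left a Spearman correlation with length of 0.06 and a median log2 fold change of 0.06 in the longest eighth. Rises that stayed in the longest genes may thus hold a remainder of the trend. All lean libraries lay on one side and all high-fat libraries on the other, so a technical source and an effect of diet on long and short transcripts stay open together.

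The second pattern is the lower ribosomal protein list in high-fat nodes. With the length and GC trend removed, camera with a preset correlation still called the list lower, at a median of -0.26. With an estimated correlation the camera adjusted p was 0.87, as for most lists. The call with the preset correlation argues against that trend as the whole cause only as far as the annotated lengths hold. Rps15a and Rps20, outside the list and chosen after their values were seen, have annotated lengths of 5130 and 3706 nt, against a list median of 820 nt. Their falls grew with the trend removed (-0.54 to -0.63 and -0.50 to -0.55). A trend with expression level on top of it cannot be told apart from a fall of these genes: with the level trend removed too the median was -0.13, with the list still called (camera adjusted p = 0.0006), but quantile normalization gave -0.05 and ended the call (adjusted p = 0.34, range over the 28 alternatives 2.8e-16 to 0.92). Ribosomal protein genes are among the most abundant here, at 7.26 ± 0.139% of summed FPKM in lean and 6.56 ± 0.119% in high-fat nodes, and why quantile normalization ended the call was not tested. Lower transcription of these genes on the high-fat diet stays open and untested.

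The third pattern is the higher mature B cell list in high-fat nodes. As far as the annotated lengths hold, the length and GC trend is argued against as its cause. With the trend removed the median was 0.27 and camera with a preset correlation still called the list. With an estimated correlation the camera adjusted p was 0.87, as for most lists. The call in the deposited values was lost without lean replicate 2 (median 0.10, camera adjusted p = 0.072), and the median with the trend removed was then 0.18. A larger share of B cells in the high-fat nodes may contribute: all 5 of the most abundant members had log2 fold changes above 0 with the trend removed, Cd37 of 0.26 (SE 0.07), Cd79b of 0.27 (SE 0.12), Ms4a1 of 0.22 (SE 0.15), Cd79a of 0.18 (SE 0.14) and Ly6d of 0.08 (SE 0.13). Of these only Cd37 passed (limma adjusted p = 0.043), and in the deposited values Ly6d was at -0.17. The 5 genes belong to the called list, in which 17 of 19 members had log2 fold changes above 0 in the deposited values. That all 5 lay above 0 was thus partly fixed in advance, and it does not tell a larger share from a change within B cells. A change within B cells stays open and untested, and with the trend removed Cr2 was higher by 0.53. That 0 genes of this list are in another list follows from how the lists were written. It does not show that the members are expressed only in B cells, so neither explanation can be settled by them.

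One hypothesis was drawn from the largest rises, since Tsc22d3 and Ddit4 are both induced by glucocorticoids: a stronger glucocorticoid response in the high-fat nodes may lie behind them. A list of 13 other glucocorticoid-induced genes was written after the gene test had prompted it, leaving out Tsc22d3, Ddit4 and Cxcr4, and 9 of them were tested. What the list should show was set down before its result was seen. With the length and GC trend removed their median log2 fold change was 0.0504 (camera unadjusted p = 0.70), too small for the hypothesis and not at or below 0, so the test decided nothing. In the deposited values the median was -0.03 (camera unadjusted p = 0.98), and Fkbp5 rose by 0.21, Pik3r1 rose by 0.35 and Mt1 fell by 0.43. With the trend removed limma called 0 of the 9, with Fkbp5 at 0.07, Pik3r1 at 0.26 and Mt1 at -0.15.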
